A study of Mus musculus with 8 samples.

How the data were processed

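Small RNA libraries were made, per the labels' protocols, with a ligation-based small RNA library kit from RNA of extracellular vesicles, which another kit had isolated from culture medium. The deposited table gives whole-number counts of reads per Ensembl gene for 8 libraries, made by the authors without normalization. The reads were aligned to the mouse build GRCm39 with STAR, and DESeq2 was also used, per the submitters' processing notes, which give no versions; the counting tool, the annotation release, the treatment of strand and of reads matching several places, and any trimming or length selection are not given in the sources used here. A miRNA gene's count sums both arms of its hairpin, and a small RNA fragment inside a long gene counts for that gene.

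Each of the 8 columns was matched to 1 sample by its state, replicate number and the number after the letter S in its label. The groups were 4 mTSC and 4 pTGC libraries. All mTSC S numbers are higher than the pTGC ones, and the labels do not say what these numbers mark. If they follow an order of processing, its effect cannot be separated from the group. The table lists 56691 features, of which 12446 had 0 counts in all libraries. Symbols came from the GENCODE release M21 annotation (build GRCm38), matched on Ensembl identifiers: 52073 features (91.9%) matched, with 85.0% of all counts. Of 2212 miRNA genes 1135 matched (51.3%), with 100.0% of miRNA counts. Because that annotation is on another build than the one used for alignment, no coordinates are given. It was used for names, gene structure and neighbours only. miRNA genes were those typed as miRNA in the deposited table (2201) plus those with a miRNA symbol (11, long noncoding host genes), of which 258 and 4 were tested.

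Totals ranged from 2055280 to 7510107 counts, with a mean 1.68 times larger in pTGC libraries. Shares of a single library are given with 95% Wilson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. Chi-square statistics per degree of freedom between libraries of a group ranged from 9.37 to 323, so every pair within a group differed by more than sampling noise.

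Features were filtered with filterByExpr, which left 12635, scaled with TMM factors (0.393 to 2.30) and tested with edgeR's quasi-likelihood F test of pTGC against mTSC in 1 model of all 8 libraries without covariates. P-values were adjusted by Benjamini and Hochberg, and 0.05 was the threshold; adjusted p-values in the text are from this test unless another is named. Standard errors are the log2 fold change divided by the square root of its F statistic. CPM are counts scaled by library size with the cpm function of edgeR, and normalised CPM use the TMM-scaled library size. Fixed lists (27, of which 22 had the minimum of 3 tested members) were tested with limma's camera on log2 CPM with a prior count of 2, with a preset correlation of 0.01, the miRNA lists against the other tested miRNA genes and the rest against all tested features, adjusted over the 22 lists. Shares of RNA classes and numbers of detected genes were compared with two-sided exact permutation tests of the difference of means. Where a group had 1 to 3 counts of a named gene, the ratio of pooled counts per scaled library size is given with its exact 95% counting interval; with 0 counts, a lower bound at 3 counts over the group.

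The genes named were set by rule: the 8 miRNA genes higher and the 8 lower with the largest log2 fold change among those past the threshold, with a mean of 10 CPM or more and no overlap between groups; the 5 other features higher and the 5 lower by the same criteria; the 5 miRNA genes with the highest mean CPM over all 8 libraries; and in each fixed list up to 4 members with the lowest p among those tested. Genes without a symbol were skipped, and of near-identical copies the one with the highest mean CPM was named. Plekhh2, mt-Ts2, mt-Tr, Mir503, Rpl32l, Snord89, Phlda2, Fgfr2, Plac8, Rny1, Col1a1, Col1a2, Col3a1, Hand1, Prl3d1, Prl2c2 and Ctsq fall outside this rule and were chosen after their values were seen. The groups, lists, tests, rule and most alternatives were fixed before the data were examined.

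Alternatives were other scalings (RLE size factors, library totals, miRNA genes alone), other filters, DESeq2, limma-voom, a fold threshold of 2, leaving out the features above 5% of any library (11), a replicate block, each library left out in turn, and for lists an estimated correlation and the fry test. Drawing all libraries down to 1 total, using mTSC libraries 1 and 2 or 3 and 4 alone, and fitting small RNA classes only were added after the data were seen. The test was tried on simulated counts for 12635 features with known changes. Of 112 calls 3 were false (2.68%), and the 1 list shifted by simulation was recovered with 0 of the other lists called. The simulated features varied independently and without a broad shift in composition between groups. This trial therefore does not give the false-call rate of the real libraries. Nor does it test camera on correlated genes, and estimated correlations within the real lists reached 0.936. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.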

Results

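The libraries hold small RNA of extracellular vesicles, the membrane-bound particles that cells shed, purified with a kit from mouse trophoblast culture medium. In all 8 libraries 70% of that medium had been conditioned by fibroblasts, so vesicles of those cells may be present too. Trophoblast stem cells (mTSC) can be kept dividing and undifferentiated with the growth factor FGF4 and heparin. Without both, and with retinoic acid added, they differentiate into giant cells (pTGC), the large polyploid cells of the outer placenta. The series holds 4 mTSC libraries, from medium taken on day 2, and 4 pTGC libraries, from medium taken on day 6, after seeding 600000 and 38000 cells per well. State, culture time, seeding density and supplements therefore differ together between the groups. Some labels conflict: the pTGC titles carry day 2 where their other fields and the deposited columns carry day 6, and 1 characteristic gives every sample the differentiation medium. Samples were grouped by cell type. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

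Counted reads numbered 2055280, 6199579, 2426615 and 4721499 in mTSC libraries 1 to 4, and 5315602, 6757701, 7510107 and 6277834 in pTGC libraries 1 to 4. Log2 counts correlated across features at r = 0.91 to 0.93 between pTGC libraries, at 0.64 to 0.77 between mTSC libraries and at 0.57 to 0.71 between groups; features are not independent replicates. The sources name the series' topic as vesicle contents of trophoblast cells with a view to fetal brain development, and the design compares the 2 states.

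The first question was which kinds of RNA the vesicle libraries held. Mitochondrial RNA made up 52.1% ± 6.02 (SD, n = 4) of counts in mTSC libraries and 20.7% ± 3.45 (n = 4) in pTGC libraries. The fall was steepest for the mitochondrial ribosomal RNAs, from 22.5% ± 3.09 to 2.59% ± 0.201, and for mitochondrial messenger RNAs, from 3.08% ± 0.420 to 0.294% ± 0.0273; mitochondrial transfer RNAs went from 26.5% ± 5.22 to 17.8% ± 3.25. Small nucleolar RNAs (snoRNAs), which guide the chemical modification of ribosomal RNA, rose from 1.03% ± 0.545 to 8.97% ± 2.36. Nuclear ribosomal RNA rose from 8.82% ± 5.02 to 17.8% ± 1.13, and the class of miscellaneous small RNAs from 2.61% ± 1.33 to 9.38% ± 0.512. Most of that class was the Y RNA Rny1, part of a cytoplasmic ribonucleoprotein, at 2.47% ± 1.26 and 8.51% ± 0.562. Small nuclear RNAs rose from 0.182% ± 0.0278 to 0.773% ± 0.0292 and long noncoding RNAs from 0.468% ± 0.217 to 1.16% ± 0.192.

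In each of these 8 classes no library of 1 group reached the range of the other. The two-sided exact permutation test gave p = 0.0286, the smallest that 70 assignments allow, and adjusted p = 0.0393 over 11 classes. Shares are parts of a whole, so a fall of mitochondrial RNA raises the others. Set against non-mitochondrial counts alone, the groups overlapped for nuclear ribosomal and long noncoding RNA. There mTSC library 3 (15.4% and 0.778% of all counts, 49.1% mitochondrial) lay above every pTGC library for nuclear ribosomal RNA. For long noncoding RNA it lay above some of them. The snoRNAs, small nuclear RNAs and miscellaneous small RNAs stayed apart. Micro RNA (miRNA) genes took 22.7% ± 10.9 and 24.9% ± 2.60, a difference of 2.21 percentage points (exact permutation p = 0.771) whose sign turned in 4 alternatives: it was −5.87 without the features above 5% of any library, −17.8 without mitochondrial features, and −0.493 or −1.03 when mTSC library 3 or 4 was left out. The class includes Snord43, typed as a miRNA in the deposited table but named as a snoRNA by the annotation. Snord43 stood at 1296 CPM of library totals in mTSC and 20290 in pTGC libraries, a rise that made up most of the 2.21 points. By its symbol Snord43 also counts among the C/D box snoRNAs below. The miRNA share was 36.0% (95% Wilson interval 35.96 to 36.09, counting error only) in mTSC library 1, 27.1% in library 2, 14.6% in library 3 and 13.0% (12.95 to 13.01) in library 4. Protein-coding genes took 11.2% ± 9.32 and 14.8% ± 2.80 (exact permutation p = 0.543), a difference that turned to −3.52 points without mitochondrial features, with 4.01% and 3.87% in mTSC libraries 1 and 2 against 13.3% and 23.5% in libraries 3 and 4. In mTSC library 4 the gene Plekhh2 alone held 18.0% of counts, against 4.54% in mTSC library 3 and at most 0.571% in the others. The remaining class held 0.934% ± 0.252 and 1.495% ± 0.491 (exact permutation p = 0.0857), a difference that turned to −0.827 points without the features above 5% of any library and −0.069 without mitochondrial features.

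**Figure D1:**
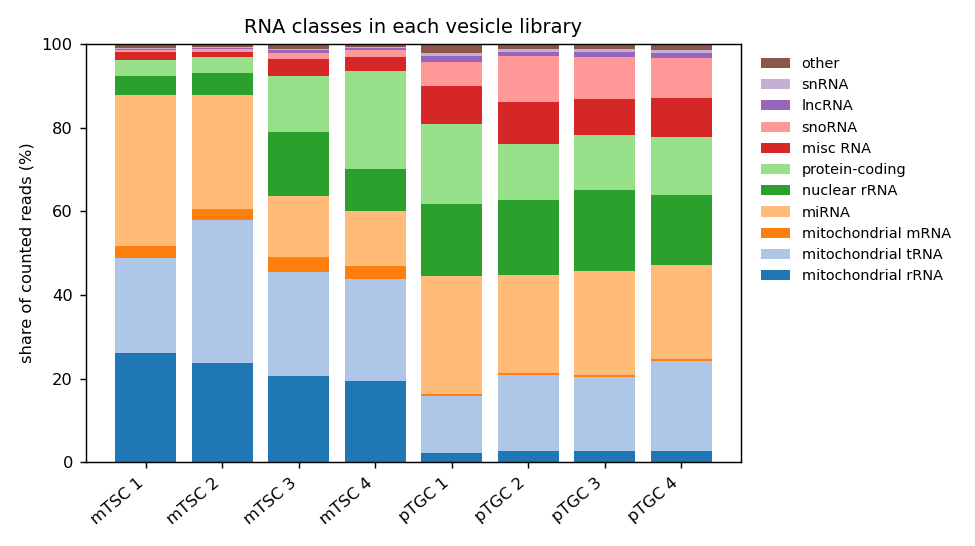
Share of counted reads (%) held by each RNA class in each library, as stacked bars for the 4 mTSC and the 4 pTGC libraries. Mitochondrial classes, at the base of each bar, sum to 47.0% to 60.7% in mTSC and 16.2% to 24.6% in pTGC libraries.

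Fragments of messenger RNAs in the vesicles differed between the mTSC and pTGC groups. Among the 16 tested genes of a list of trophoblast stem cell genes, 10 fell in pTGC vesicles. Sox2, a transcription factor of stem cells, fell from 22.8 ± 7.64 to 1.47 ± 0.486 normalised CPM (SD, n = 4 each; log2 fold change −3.96 ± 0.35 SE, adjusted p = 2.66e-06). Eomes and Cdx2, transcription factors that set up the trophoblast lineage, fell by 4.52 ± 0.41 and 4.74 ± 0.51 on the log2 scale, and the nuclear receptor Esrrb by 2.75 ± 0.33. Of 13 tested giant cell genes 8 rose. The list had 34 genes in the table, and the rest, such as Prl3d1, Prl2c2 and Ctsq, did not pass the count filter. Hand1, also on the list, was tested. Its pooled counts (173 in mTSC and 845 in pTGC libraries) did not rise per TMM-scaled library size. The homeobox genes Rhox6 and Rhox9 rose by 3.74 ± 0.43 and 3.85 ± 0.45, and Tfpi, an inhibitor of coagulation, by 2.96 ± 0.35. Plac1, a placental surface protein gene, had 3 counts over the mTSC libraries and 468 over the pTGC libraries, a pooled normalised ratio of 29.0 (exact counting interval 9.87 to 141).

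Adjusted over the list alone, 11 stem cell genes and 9 giant cell genes changed. Both lists moved against all other tested features in limma's camera test with a preset correlation (adjusted p = 3.19e-10 and 5.79e-06). With an estimated correlation neither did (adjusted p = 0.0920 and 0.132). With the stricter low-count filter the stem cell list was no longer past the threshold (adjusted p = 0.134). Scaled to library totals alone, where the median of all tested features was 1.72 instead of 0.09, 7 stem cell genes still fell and 3 rose, and Fgfr2 turned from −1.44 to 0.05; all 13 giant cell genes rose. Plac8, with 0 counts in mTSC and 118 in pTGC libraries, was at least 7.31-fold higher against a floor of 3 counts over the group, and the giant cell median was 2.42 with Plac8 as fitted and with it at that bound.

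**Figure D2:**
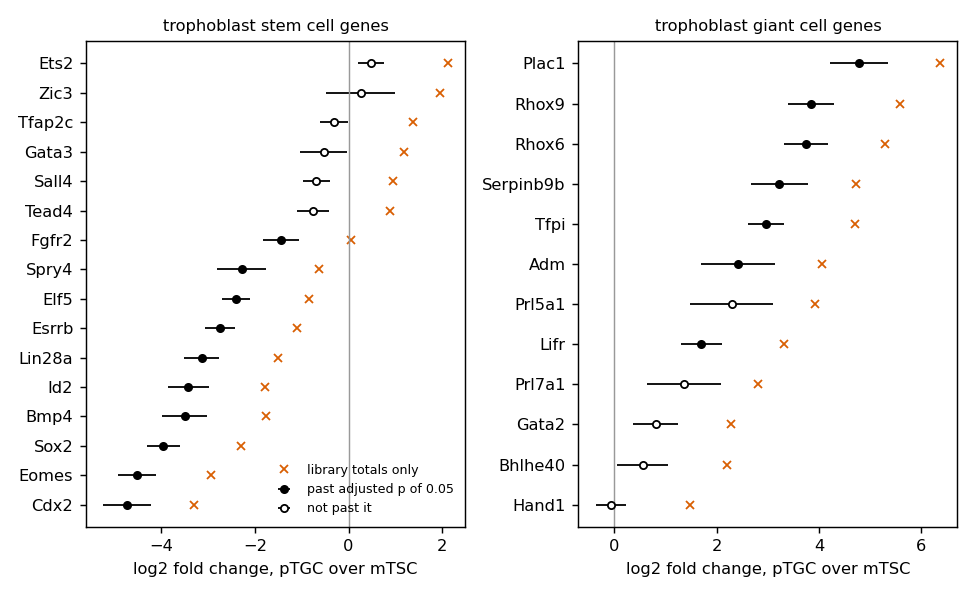
Log2 fold change, pTGC over mTSC, of the tested stem cell genes (left) and giant cell genes (right; Plac8, with 0 mTSC counts, is not drawn); circles with bars are edgeR estimates with SE, filled where the adjusted p is under 0.05, and crosses are the estimates with library totals only. Of the stem cell genes, 10 are filled and left of 0, and Fgfr2 lies at 0.05 when scaled to library totals; Plac1 at 4.79 rests on 3 mTSC counts.

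Across all 12635 tested features, 2629 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1535 higher and 1094 lower in pTGC vesicles, and 4331 had an unadjusted p under 0.05. With library totals only, 8215 were higher and 135 lower, so each direction given here is relative to the bulk of the features, most of them fragments of 10896 protein-coding genes. Nuclear ribosomal RNA, whose share of counts rose, had 16 features lower and 5 higher of 60 tested. Its share did not rise evenly over features. ENSMUSG00002075795 held 1.96% ± 0.822 of counts in mTSC and 7.83% ± 0.837 in pTGC libraries. ENSMUSG00000119584 held 6.10% ± 3.84 and 6.44% ± 0.853. In simulated libraries of these 12635 features the test recovered 5.97% of the 67 features changed by a factor of 2, 62.7% of 67 changed by 4 and 95.5% of 66 changed by 8.

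By the fixed rule the largest rises outside the miRNA genes were in Serpinb9f, Serpinb9e, Gm19368, H2-K1 and Cmklr1. Serpinb9f and Serpinb9e belong to a placental cluster of serine protease inhibitors with near-identical copies, so reads may be split between them. Serpinb9f had 1 mTSC and 718 pTGC counts (pooled ratio 134, exact counting interval 23.9 to 5280), and Serpinb9e rose from 0.401 ± 0.584 to 34.1 ± 3.04 normalised CPM (log2 6.11 ± 0.52, adjusted p = 2.57e-06). The pseudogene Gm19368 had 2 and 515 counts (ratio 47.9, interval 13.2 to 396). H2-K1, a major histocompatibility class I gene, rose by 5.48 ± 0.50, and Cmklr1, the receptor of the chemoattractant chemerin, by 5.28 ± 0.43. The largest falls were in the mitochondrial transfer RNA mt-Te (−7.26 ± 0.76), Tysnd1, a peroxisomal protease gene (−5.78 ± 0.49), the long noncoding RNA Gm15498 (−5.45 ± 0.73), mt-Nd6 (−5.34 ± 0.46) and mt-Cytb (−5.31 ± 0.58), the last 2 encoding parts of the respiratory chain. All of these kept their direction with library totals only.

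Mitochondrial transcripts fell nearly as a block. All 9 tested messenger and ribosomal RNAs of mitochondria fell, with a median of −5.05; mt-Nd1, mt-Nd4 and mt-Nd5, subunits of respiratory complex I, fell by 5.05 ± 0.50, 5.05 ± 0.46 and 5.14 ± 0.52. Of 15 tested mitochondrial transfer RNAs 14 fell, such as mt-Tl2 (−4.65 ± 0.56), mt-Tt (−3.38 ± 0.47) and mt-Tn (−2.69 ± 0.43). Under library totals the 9 messenger and ribosomal RNAs fell again, and 9 transfer RNAs fell while 1 rose, with mt-Tr turning from −1.81 to 0.04 and mt-Tn no longer called (−1.13, adjusted p = 0.0868). The 1 that rose there was mt-Ts2, at 0.30 ± 0.57 (adjusted p = 0.752) in the main scaling and 2.00 with library totals, and its share of counts was 1.98% ± 0.715 in mTSC and 7.80% ± 1.40 in pTGC libraries. Over the list alone 9 and 14 changed, camera gave adjusted p = 1.57e-19 and 4.67e-14, and with an estimated correlation adjusted p = 0.0920 and 0.132.

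Most of the tested snoRNAs on the fixed lists rose. Of 34 tested C/D box snoRNAs, which guide ribose methylation, 27 rose and 1 fell. Snord61 rose from 24.2 ± 8.38 to 367 ± 138 normalised CPM (log2 3.94 ± 0.44, adjusted p = 1.75e-05), Snord98 by 4.43 ± 0.53, Snord123 by 3.32 ± 0.40 and Snord7 by 2.13 ± 0.32. Of 17 tested H/ACA box RNAs, which guide pseudouridylation, and Cajal body RNAs, 10 rose. Among them were Snora31 (2.79 ± 0.43), Snora78 (3.30 ± 0.57), Scarna6 (2.69 ± 0.47) and Scarna10 (2.10 ± 0.39). Over each list alone, 30 and 12 changed. Camera gave adjusted p = 8.26e-10 and 0.000411, and with an estimated correlation adjusted p = 0.426 for both. Snord89, the 1 member that fell (−1.44 ± 0.34), stood at 0.10 with library totals. The snoRNA share differed between pTGC libraries, at 5.56% in library 1 and 9.39% to 10.9% in the rest.

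Rnu12, the minor spliceosome's U12 RNA, rose by 1.69 ± 0.33, and the other RNA caught by the small nuclear RNA pattern, Rnu73b, which the deposited table types as a snoRNA, stood at 0.27 ± 0.35 (adjusted p = 0.626) and at −0.024 with the stricter filter. Of 6 tested cytoplasmic structural RNAs, the Y RNA Rny3 rose (1.36 ± 0.39, adjusted p = 0.0193, and 0.0512 to 0.0561 without mTSC library 2, pTGC library 2 or pTGC library 3, 0.0503 against mTSC libraries 3 and 4 alone and 0.0567 with small RNA classes only), the brain-enriched Bc1 fell (−2.65 ± 0.55, adjusted p = 0.00299; −1.08 and 0.121 with library totals) and Rny1 stood at 0.28 ± 0.56, against 1.80 with library totals; over the list alone 4 changed, and the camera adjusted p was 0.451.

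Some histone and ribosomal protein transcripts fell relative to other fragments, and none of these falls passed the threshold with library totals. Of 28 tested histone genes of the replication-dependent kind, made during DNA synthesis, 14 fell, with Hist1h1d at −2.21 ± 0.30, Hist4h4 at −1.90 ± 0.34, Hist1h1c at −2.13 ± 0.43 and Hist1h1e at −1.55 ± 0.30. With library totals 4 rose, and Hist1h1e turned to 0.12. Of 56 tested ribosomal protein genes 10 fell, such as Rps20 (−1.69 ± 0.30), Rps15 (−1.53 ± 0.32) and Rpl37 (−1.93 ± 0.49). Another 2 rose, Rpl7a by 2.89 ± 0.56 and Rpl32l by 2.21 ± 0.69. With library totals 19 rose, with Rps20 at 0.0060 and Rps15 at 0.11. Like the snoRNA Snord123, Rpl7a was low in pTGC library 1 (146.5 normalised CPM, against 519.5 to 594.9 in the other pTGC libraries). Whether the reads of Rpl7a came from its messenger RNA was not tested. Over the lists alone, 16 and 18 changed. Camera gave adjusted p = 1.48e-08 and 8.90e-07, and with an estimated correlation adjusted p = 0.0920 and 0.107.

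Among 13 tested imprinted and hypoxia genes, 4 imprinted genes rose: Cdkn1c, a cell cycle inhibitor (2.10 ± 0.32), H19 (2.14 ± 0.42), Peg3 (1.65 ± 0.33) and Peg10 (1.31 ± 0.32), the last needed for placenta formation. Phlda2, which restrains placental growth, fell by 1.40 ± 0.36 and turned to 0.27 with library totals. Over this list alone 5 changed, and the camera adjusted p was 0.311, but 0.0363 without a count filter, and fry gave adjusted p = 0.000542. Of 5 tested spongiotrophoblast and syncytiotrophoblast genes 3 rose: Slc16a1, a lactate transporter (2.01 ± 0.31), Ly6e (1.28 ± 0.37, adjusted p = 0.01995, and 0.0553 to 0.0583 without mTSC library 3 or pTGC library 1, 2 or 3) and Psg17, a pregnancy-specific glycoprotein gene with 3 mTSC and 237 pTGC counts (ratio 14.7, exact counting interval 4.97 to 71.7). The call of Ly6e also ended with counts drawn down (adjusted p = 0.133), against mTSC libraries 1 and 2 alone (0.113) and with a replicate block (0.0692). Over that list alone 3 changed, the camera adjusted p was 0.0719 and that of fry 0.000138.

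Markers of fibroblasts, which conditioned part of the medium (70% in both groups), did not pass the camera test as a list. Of 13 tested fibroblast genes 3 rose, also over the list alone: Pdgfra (3.34 ± 0.41), Col5a1 (1.95 ± 0.31) and Postn (1.92 ± 0.49). Col1a1, Col1a2 and Col3a1, the abundant fibroblast collagens, stood at −0.22 ± 0.42, 0.16 ± 0.50 and −0.50 ± 0.63. The list's median was −0.11, its mean 0.48, and the camera adjusted p 0.539 with a direction towards higher. The fry test called it higher (adjusted p = 0.0416), and with library totals 10 members rose.

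The second question was which miRNAs differed. The cluster of Mir322 and Mir503, neighbouring X-linked miRNA genes known to act on the cell cycle, rose as a whole: all 5 tested members rose, adjusted over all features and over the list alone, and under each of 3 scalings. Mir322 rose from 379 ± 75.2 to 2675 ± 332 normalised CPM (log2 2.82 ± 0.39, adjusted p = 0.000138), Mir351 by 2.78 ± 0.42, Mir450b by 2.40 ± 0.34, Mir542 by 1.54 ± 0.32 and Mir503 by 1.38 ± 0.42. Mir450-1, which sits beside them and was not on the list under that symbol, rose by 4.48 ± 0.41. The cluster's camera adjusted p was 1.39e-05, but 0.132 with an estimated correlation and 0.0561 with miRNA-only scaling.

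The other named rises were Mir135b (5.28 ± 0.46, adjusted p = 2.57e-06), Mir455 (2.63 ± 0.47), Snord43 (2.46 ± 0.56) and Mir670hg (2.11 ± 0.39). Snord43 is typed as a miRNA in the deposited table and named as a snoRNA by the annotation used for symbols, and Mir670hg is a long noncoding host transcript. The largest falls were in Mir375, known from pancreatic islets and neuroendocrine cells (2051 ± 1230 to 32.1 ± 5.15 normalised CPM, log2 −6.00 ± 0.54, adjusted p = 2.66e-06), Mir1968 (−5.34 ± 0.58), Mir181c (−5.13 ± 0.57), Mir181d (−5.09 ± 0.51), Mir130b (−4.90 ± 0.61), Mir1947 (−4.87 ± 0.52), Mir672 (−4.76 ± 0.68) and Mir99a (−4.30 ± 0.71). Each of these 16 kept its direction and its call with library totals and with miRNA genes scaled among themselves. The miRNA genes with the highest mean CPM over all 8 libraries were Mir669c, Mir148a, Mir183, Snord43 and Mir423, an order that differed within each group: Snord43 stood at 1296 CPM of library totals in mTSC against 20290 in pTGC libraries, and Mir672 at 13340 in mTSC libraries exceeded Mir183 at 8471. Mir669c fell by 3.04 ± 0.76, a call that ended without pTGC library 4 (adjusted p = 0.0576); Mir148a fell by 3.41 ± 0.79; Mir423 fell by 2.30 ± 0.57 and stood at −0.44 with library totals (adjusted p = 0.254). Mir183 stood at −0.22 ± 0.51 (adjusted p = 0.806), and was higher at 1.55 with library totals (adjusted p = 0.000482) and at 0.83 with miRNA-only scaling (adjusted p = 0.0125).

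**Figure D3:**
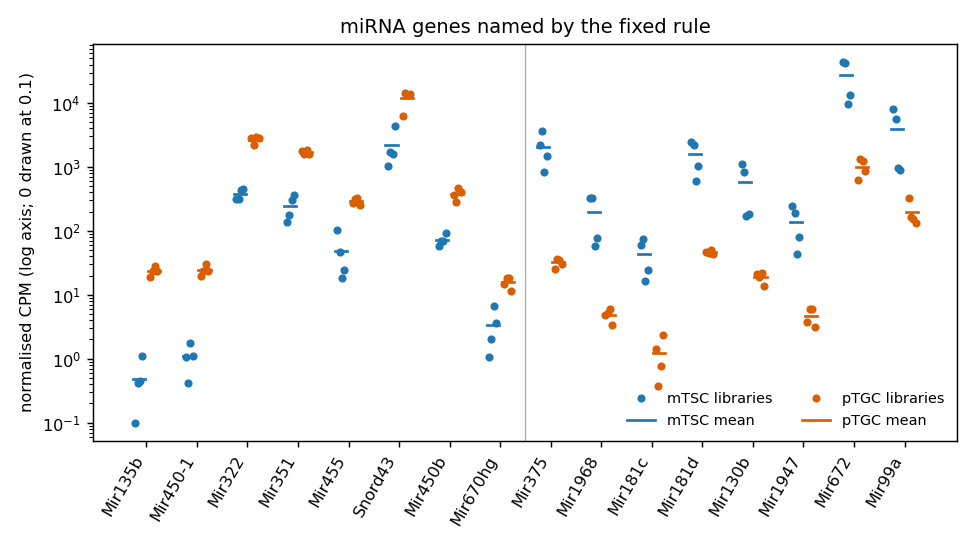
Normalised CPM, on a log axis, of the 8 miRNA genes with the largest rise (left of the line) and the 8 with the largest fall (right) in pTGC vesicles; points are the 4 mTSC and 4 pTGC libraries and bars their means. Mean Mir375 goes from 2051 in mTSC to 32.1 in pTGC libraries, and mean Mir322 from 379 to 2675.

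Of 262 tested miRNA genes, 122 changed, 21 higher and 101 lower, or 144 (23 and 121) adjusted over the list alone. This balance followed the scaling: library totals gave 94 higher and 38 lower, and miRNA genes scaled among themselves 72 higher and 62 lower of 270 tested. The median log2 fold change of miRNA genes was −1.14 in the main scaling, 0.68 with totals and 0.03 with miRNA genes alone. Across all 3 scalings 21 genes were called higher each time and 38 lower each time, and 0 were called opposite ways by the main and the miRNA-only fit. The balance also followed the mTSC libraries: against mTSC libraries 1 and 2 alone 16 were higher and 177 lower, and against libraries 3 and 4 alone 48 and 62.

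**Figure D4:**
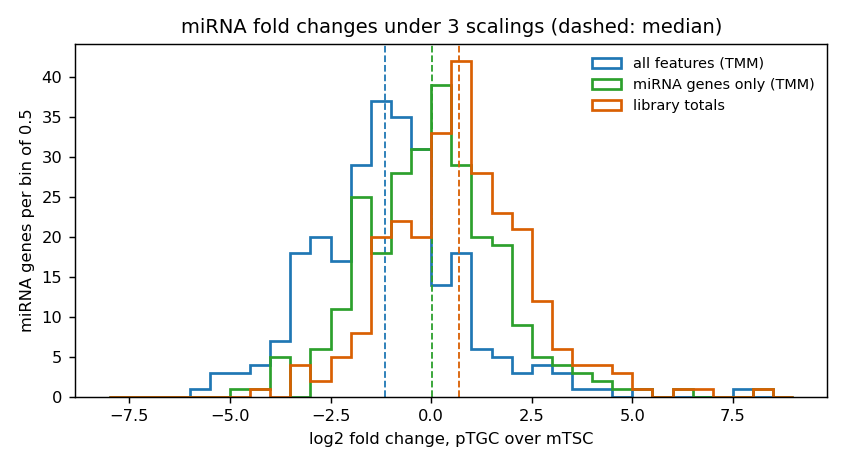
Histograms of log2 fold changes, pTGC over mTSC, of the tested miRNA genes under 3 scalings, in bins of 0.5 with dashed lines at the medians. The medians lie at −1.14 (all features), 0.03 (miRNA genes only) and 0.68 (library totals).

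No other miRNA list passed the camera test, and their directions are relative to the main scaling. Among 10 tested neural miRNAs 6 fell (7 over the list alone; camera adjusted p = 0.241): Mir128-1 and Mir128-2, enriched in neurons, fell by 4.21 ± 0.57 and 4.01 ± 0.53, and Mir218-1 and Mir218-2, of motor neurons, by 3.82 ± 0.62 and 3.22 ± 0.47. With miRNA-only scaling these 4 fell and 2 others rose. In the imprinted Dlk1-Dio3 cluster 10 of 19 fell (13 over the list alone; adjusted p = 0.409), with Mir543 at −3.44 ± 0.57, Mir495 at −3.29 ± 0.59, Mir329 at −2.34 ± 0.45 and Mir666 at −2.47 ± 0.50; with miRNA-only scaling 6 fell and 2 rose. In the Sfmbt2 cluster, a large rodent miRNA family active in placenta whose members are near-identical and so uncertain, 4 of 14 fell (6 over the list alone; adjusted p = 0.906): Mir669h at −4.16 ± 0.65, Mir669c, Mir466g at −1.97 ± 0.49 and Mir669a-3 at −2.16 ± 0.60, whose call ended without mTSC library 2 or pTGC library 2 (adjusted p = 0.187 and 0.0574) and which stood at 0.35 against mTSC libraries 3 and 4 alone; limma-voom (adjusted p = 0.214) and a replicate block (0.0565) did not call it. In this cluster miRNA-only scaling gave 5 higher and 2 lower.

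In the let-7 family, regulators of differentiation, Mirlet7g rose by 1.88 ± 0.46 and Mirlet7c-1 fell by 2.32 ± 0.47 of 4 tested (2 over the list alone; adjusted p = 0.624). In the miR-200 family, which keeps epithelial character, Mir200c fell by 2.83 ± 0.36 of 3 tested (1 over the list alone, camera adjusted p = 0.920). Mir200b stood at 0.82 ± 0.44, with a call as higher under totals (2.62) and miRNA-only scaling (1.91). It was also called higher against mTSC libraries 3 and 4 alone (1.56, adjusted p = 0.0117) and with small RNA classes only (1.13, 0.00228). In the miR-15/16 family of 6, Mir322 rose and Mir195a fell by 2.72 ± 0.52 (4 over the list alone; adjusted p = 0.402). Of 3 tested members of the miR-34 family Mir34c and Mir34b fell by 2.497 ± 0.53 and 2.07 ± 0.45 (2 over the list alone, camera adjusted p = 0.539). Of 3 tested in the miR-17 clusters Mir92-2 fell by 1.63 ± 0.41 (1 over the list alone, camera adjusted p = 0.624), but stood at 0.19 with totals. Mir106b stood at −0.93 ± 0.43 and was called in both directions by other settings. It was called higher with totals (0.95, adjusted p = 0.0374) and stood at 0.24 with miRNA-only scaling. It was called lower with the stricter filter (−1.24, adjusted p = 0.0452), without mTSC library 3 (−1.21, 0.0302) and against mTSC libraries 1 and 2 alone (−1.39, 0.00514). Among 11 fibroblast miRNAs Mir196a-1 and Mir10b fell by 2.57 ± 0.71 and 1.53 ± 0.43 (3 over the list alone; adjusted p = 0.442), Mir10b turning to 0.32 with totals, and miRNA-only scaling gave 4 higher and neither of these as a fall. Limma-voom did not call Mir196a-1 (adjusted p = 0.278). Both calls ended without mTSC library 2 (adjusted p = 0.0654 and 0.0672) or pTGC library 4 (0.0533 and 0.0585), and that of Mir10b also without pTGC library 2 or 3 (0.0562 and 0.0570). The medians of the let-7 list (−0.69), the miR-15/16 list (−0.81) and the fibroblast miRNA list (−0.48) lay below 0 while camera, which sets each against the other miRNA genes, pointed higher. Too few were tested for a set test among blood miRNAs (Mir150 at −2.97 ± 0.45, Mir144 at 0.43 ± 0.56, called higher at 2.40 with totals and 1.65 with miRNA-only scaling) and muscle or liver miRNAs (Mir499 at −1.61 ± 0.42, and 0.25 with totals). Mir144 was also called higher against mTSC libraries 3 and 4 alone (1.91, adjusted p = 0.0480), and turned to −0.35 against libraries 1 and 2 alone. Several calls among these lists ended, without a turn of sign, under other scalings or with fewer mTSC libraries. With library totals those of Mir34c, Mir34b, Mirlet7c-1, Mir195a, Mir466g, Mir669a-3, Mir329, Mir666 and Mir196a-1 ended, at −0.81 to −0.14 (adjusted p = 0.107 to 0.787). With miRNA-only scaling those of Mir34b, Mir92-2, Mir466g, Mir669a-3, Mir196a-1, Mir10b and Mir499 ended, at −1.31 to −0.36 (adjusted p = 0.0515 to 0.202). Against mTSC libraries 3 and 4 alone those of Mir34c, Mir34b, Mirlet7c-1, Mir466g, Mir666, Mir196a-1, Mir10b and Mir499 ended, at −1.32 to −0.45 (adjusted p = 0.0674 to 0.385). None of 9 miR-290 and 5 miR-302 genes in the table passed the count filter. Mir291a, Mir291b, Mir292, Mir292b, Mir293, Mir294 and Mir295 overlap exons of Nlrp12 and had 0 counts. Untested let-7 and miR-17 cluster genes such as Mirlet7b and Mir17 also overlap exons and had 0 counts. Reads over 2 annotated genes may have been left out of the counts. For these genes the counts therefore do not show absence from the vesicles. Mir302a, Mir302b, Mir302c and Mir302d overlap no annotated exon.

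The last question was how many miRNA genes each library showed. Drawn down to 2055280 counts per library, 177.5 ± 22.5 miRNA genes had 10 or more counts in mTSC and 204 ± 9.49 in pTGC libraries, a difference of 26.5 (two-sided exact permutation test, p = 0.0571). The difference passed the threshold, at p = 0.0286 each in the exact permutation test, with a minimum of 1 count (110 genes), with counts as deposited (87 genes) and with libraries drawn down to the same miRNA total (16.25 genes). It did not with a minimum of 50 counts (15.25 genes, exact permutation p = 0.0571).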

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

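Except for the test of shared sequence between miRNA genes and the test of nuclear RNAs, the tests in this part were chosen after the result was seen.

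In 16 of 230 groups of 4 libraries, 1 library lay far from the other 3 for the spread of the group (its gap to the nearest divided by the range is given as the gap ratio); chance alone gives about 1 in 20 groups, or 11.5. In pTGC library 1, 7 values stood apart from the others. The snoRNAs Snord43 (6330 against 13390 to 14440 normalised CPM, gap ratio 0.870), Snord123 (33.7 against 90.3 to 101, 0.838), Snora78 (4.27 against 7.77 to 8.23, 0.884) and Scarna6 (10.2 against 21.4 to 23.2, 0.857) were low there, as were Pdgfra (28.2 against 43.0 to 45.1, 0.874) and Rpl7a (147 against 519.5 to 595, 0.832). The protein-coding share was high there (18.98% against 13.0% to 13.9%, 0.838).

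In pTGC library 4, H2-K1 (18.0 against 23.0 to 23.8 normalised CPM, gap ratio 0.864), Mir423 (4241 against 5361 to 5477, 0.907) and Peg10 (251 against 337 to 352, 0.851) were low, and in pTGC library 2 Mir669a-3 was (2.43 against 4.12 to 4.28, 0.914). Among mTSC libraries, Mir200c was low in library 3 (346 against 587 to 594, 0.971), Bc1 high in library 1 (15.15 against 3.30 to 5.27, 0.834) and Peg3 high in library 4 (24.1 against 10.8 to 12.8, 0.851). Serpinb9f and Gm19368 were seen in mTSC library 2 alone of the 4 (0.41 and 0.83 against 0, gap ratio 1.0 for both), which rests on 1 and 2 counts.

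In edgeR 2629 features changed with the real groups. Only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many, the highest other giving 0. With 35 splits the share cannot go below 1 in 35. Every other split mixed the groups and so widened the spread within them, which leaves few calls. The splits therefore do not exclude chance for this number. The same holds for miRNA genes, with 122 against a highest other of 0 (1 of 35 splits). For the number of lists past the threshold in camera the splits do not exclude chance either: 9 passed with the real groups. Of the 35 splits 9 gave 9 or more, the highest other giving 10. The other 8 of these all kept 3 libraries of each group together and so held part of the real difference. The 18 splits that parted each group 2 and 2 gave at most 4 lists.

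Many well-known miRNA genes had no counts in any library, among them Mir21a, Mir17, Mir92-1, Mir25, Mir93, Mir191, Mir22 and Mir30d, named after their values were seen; 479 of 1124 miRNA genes placed on the annotation were at 0. A biological absence of miRNAs lying in exons of their own host transcript is argued against, since among genes sharing no 20-base stretch with another miRNA gene 83.3% (30 of 36) of those overlapping only exons on the opposite strand were at 0, against 22.8% (143 of 627) of those overlapping none (Fisher's exact test, p = 1.86e-13). A candidate explanation is that reads over 2 annotated genes were left out of the counts: among the same single-copy genes 81.5% (212 of 260) of those with exon overlap on either strand were at 0 (Fisher's exact test, p = 1.04e-60). Reads shared between copies may add to it, since among genes without exon overlap 40.7% (72 of 177) of those sharing a 20-base stretch with another were at 0 (Fisher's exact test, p = 5.12e-06). Of the fixed miRNA lists' members with exon overlap 82.1% (55 of 67) were at 0, so a miRNA missing from the table may still have been in the vesicles.

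More features had 10 or more counts in pTGC (15831 to 17038) than in mTSC libraries (2058 to 6790). Greater depth is argued against as the whole cause, since at equal totals of 2055280 counts the lowest pTGC library showed 7555 and the highest mTSC library 5062. Mitochondrial and dominant features taking most mTSC counts may account for it: without them, at equal totals of 445749 counts, the means were 3169 ± 1414.5 (SD, n = 4) and 3876.5 ± 524 (n = 4; exact permutation p = 0.371), which does not show that the groups were alike. At that lower total with all features kept, the groups stayed apart, with at most 812 in mTSC and at least 1519 in pTGC libraries (exact permutation p = 0.0286). Nuclear RNA from dying cells stays open. Nuclear long noncoding RNAs had a median log2 fold change of 0.59 over 8 tested, at percentile 86.7 of 10000 random lists (median 0.12). Malat1 (2.24 ± 0.33), Firre (2.00 ± 0.54) and Xist (1.66 ± 0.32) were called higher. Kcnq1ot1 (−0.46 ± 0.49) and Pvt1 (−0.77 ± 0.45) were negative, and none was called lower. A difference in vesicle or cell content between the states was not tested and also stays open.

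Among changed miRNA genes 101 were lower and 21 higher. Normalization to fragments of long RNAs and a real change in the ratio of miRNAs to other RNAs cannot be told apart as its source. With factors from miRNA genes alone 46.3% of calls were lower, but such factors centre the miRNA genes (median log2 fold change 0.03), which fixes a near-even balance under either explanation.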

How the results depend on the processing

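Drawing libraries down, using mTSC libraries 1 and 2 or 3 and 4 alone, and fitting small RNA classes only were chosen after the data were seen. Over all alternatives 1887 values of named genes kept direction and side of the threshold, 55 lost and 11 gained the threshold and 18 reversed; of list tests 406 kept both, 11 lost it, 4 gained it and 19 reversed. Against 2629 features changed, library totals gave 8350 (8215 higher, 135 lower), the stricter filter 1413 (706 and 707), drawing down 1739 and small RNA classes 270, the last 2 with fewer counts or features; no filter gave 2362 higher and 873 lower. Against 122 miRNA genes, mTSC libraries 1 and 2 alone gave 193. DESeq2 called 3322 features and 134 miRNA genes, limma-voom 2735 and 103, without Mir669a-3 (adjusted p = 0.214) and Mir196a-1 (0.278). In camera 9 of 22 lists passed. Small RNA classes left 14 lists to test, of which 4 passed, and miRNA genes only left 10, of which 0 passed (1 unadjusted). With an estimated correlation 0 of 22 passed (7 unadjusted). Fry called 12, among them the spongiotrophoblast, imprinted and fibroblast gene lists (adjusted p = 0.000138, 0.000542 and 0.0416), and without a filter the imprinted list passed camera (0.0363). With library totals, which raise the median log2 fold change to 1.72, these reversed: Mir183 (1.55), Mir106b (0.95), Mir10b (0.32), Mir499 (0.25), Mir92-2 (0.19), Hist1h1e (0.12), Rps15 (0.11) and Rps20 (0.0060), and the list tests of miR-200 (adjusted p = 0.877) and Sfmbt2 (0.688). With miRNA genes only, Mir183 (0.83), Mir106b (0.24) and the miR-200 and Sfmbt2 lists (0.721 for both) reversed. The cause of the following reversals was not tested. Mir183 turned to 0.13 without a filter, 0.45 with mTSC libraries 3 and 4 alone and 0.055 with small RNA classes; Mir144 to −0.35 with mTSC libraries 1 and 2 alone; Mir669a-3 to 0.35 with libraries 3 and 4 alone; Rnu73b to −0.024 with the stricter filter. List tests that turned were let-7 (0.673 without a filter, 0.983 with mTSC libraries 1 and 2, 0.739 in fry), fibroblast genes (0.493 with mTSC libraries 1 and 2), fibroblast miRNAs (0.758 in fry), Sfmbt2 (0.99885 with the stricter filter, 0.895 without dominant features, 0.629 with mTSC libraries 3 and 4, 0.953 with small RNA classes), and miR-200 and structural RNAs (0.934 for both with small RNA classes). The miRNA share difference was −5.87 points without dominant and −17.8 without mitochondrial features; the other class's was −0.827 and −0.069, and that of protein-coding genes −3.52 without mitochondrial features. Detected miRNA genes differed by 110.0 at 1 count, 87.0 as deposited and 16.25 at equal miRNA totals, each then past the threshold, and by 15.25 at 50 counts, which was not. Leaving out each library gave 1831 to 2929 features, 100 to 160 miRNA genes, 9 lists each time, 20 to 33.3 detected miRNA genes and miRNA share differences of −1.03 to 6.65. Mir183 ranged from −0.42 to 0.052 (without mTSC 2), Mir144 from −0.14 (without pTGC 1) to 1.47, and list tests from 0.595 to 0.986 for let-7 (turned without mTSC 4), 0.574 to 0.981 for Sfmbt2 (turned without mTSC 1 or pTGC 1) and 0.386 to 0.959 for fibroblast genes (turned without mTSC 3, at 0.681). Calls ended for Mir669c (adjusted p = 0.0576 without pTGC 4), Mir669a-3 (0.187 and 0.0574 without mTSC 2 or pTGC 2), Mir196a-1 (0.0654 and 0.0533 without mTSC 2 or pTGC 4), Mir10b (0.0562 to 0.0672 without mTSC 2, pTGC 2, 3 or 4), Rny3 (0.0512 to 0.0561 without mTSC 2, pTGC 2 or 3; also 0.0503 with mTSC libraries 3 and 4 alone and 0.0567 with small RNA classes) and Ly6e (0.0553 to 0.0583 without mTSC 3, pTGC 1, 2 or 3). With 3 libraries against 4 the exact permutation test of a class share cannot go below 0.0571. The libraries share only a replicate number: same-number deviations correlated at −0.06 to 0.07, 2 of 4 mTSC libraries correlated best with their own number, and a replicate block gave 1939 features, 106 miRNA genes and 9 lists, and among named genes no longer called Ly6e (adjusted p = 0.0692) and Mir669a-3 (0.0565). Of simulated changes by a factor of 2, 5.97% were recovered at the depth of these libraries; depth was not separated from the spread between libraries.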

Other observations

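The lists in this part and their tests were chosen after the values were seen; Fisher's exact test compares each with the other tested protein-coding features, ignores correlation among genes, and is adjusted over 6 tests.

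Of 9 tested genes that respond to retinoic acid, which was added to the pTGC medium, 7 rose in pTGC vesicles, in a list drawn up after values were seen (adjusted p = 1.405e-05; 1159 of the 10887 other protein-coding genes rose), and 5 of 7 without Cyp26b1 and Tgm2, which prompted the list (adjusted p = 0.000362). Cyp26b1, an enzyme that degrades retinoic acid, rose by 5.05 ± 0.44 (log2 fold change, SE, n = 4 per group), the transglutaminase gene Tgm2 by 4.99 ± 0.46, the retinal reductase gene Dhrs3 by 3.62 ± 0.39, Nrip1 by 2.81 ± 0.30, the retinol-binding protein gene Rbp1 by 2.07 ± 0.36 and Cyp26a1 by 1.44 ± 0.39. Stra6, the retinol transporter, had 3 mTSC counts (ratio 10.3, exact counting interval 3.46 to 50.4). Hoxa1 and Rarb were not called, at 0.23 ± 0.52 and 0.20 ± 0.63 (adjusted p = 0.795 and 0.855). The list's median was 2.81, and 4.45 with library totals.

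Some feedback genes of FGF and ERK signalling, a pathway that FGF4 in the mTSC medium activates, fell relative to other fragments. Of 15 tested, 9 fell (adjusted p = 1.14e-06), and 8 of 14 without Spry4, which prompted the list (adjusted p = 4.71e-06). Etv4, a transcription factor induced by FGF, fell by 3.09 ± 0.42, the ERK phosphatase gene Dusp6 by 3.07 ± 0.61, Myc by 2.33 ± 0.41, the signalling inhibitor genes Spred2, Spry2 and Spred1 by 2.16 ± 0.29, 1.74 ± 0.50 and 1.63 ± 0.52, Ccnd1 by 1.85 ± 0.59 and Egr1 by 1.67 ± 0.45. Dusp5, Fos and Il17rd stood on the other side at 1.90 ± 0.88, 0.77 ± 0.46 and 0.28 ± 0.45, not past the threshold. The list's median was −1.67 in the main scaling and 0.0039 with library totals, where Spred1 and Egr1 turned to 0.073 and 0.0039. There 1 of the 15 was called lower, Etv4 (−1.51, adjusted p = 0.0207), and 3 higher, Dusp5 (3.61, adjusted p = 0.00112), Fos (2.24, 0.00399) and Il17rd (1.86, 0.0112), and Dusp6 lost its call (−1.31, 0.0781).

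The Serpinb9 family of protease inhibitors, whose near-identical copies make single members uncertain, rose in all 7 tested members (adjusted p = 9.49e-07). Without Serpinb9e and Serpinb9f, which prompted the list, 5 of 5 rose (adjusted p = 2.76e-05). These 5 are not independent support, since reads may be split between copies and Serpinb9b was already on the fixed giant cell list. Serpinb9c rose by 4.85 ± 0.54, Serpinb9b by 3.23 ± 0.56 and Serpinb9 by 2.55 ± 0.57. Serpinb9g had 3 mTSC counts (ratio 8.93, exact counting interval 2.99 to 43.8), and Serpinb9d, with 0 mTSC counts, was at least 12.3-fold higher against a floor of 3 counts over the group. The family's median was 4.85, or 3.63 with Serpinb9d at that bound.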
